A study of Mus musculus with 10 samples.

How the data were processed

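Placentas of ICR mice, an outbred stock, were profiled by sequencing of ribosomal RNA-depleted total RNA with a directional library kit and paired-end reads. Per the labels, pregnant mice received phosphate-buffered saline (PBS) or bacterial lipopolysaccharide (LPS) at gestational day 15.5 for 48 hours, and each library pooled 6 to 8 placentas of 1 sex from 3 pregnant mice. The libraries therefore measure pools and not individual animals, and the p-values of single genes below measure the spread between pools. The labels do not say whether female and male pools came from the same mothers. The tests over both sexes treat all pools as independent, which would not hold if mothers were shared. P-values of gene lists are explained with their tests. The labels give an LPS dose whose unit is implausible, so no dose is stated here. The 10 libraries form 4 groups: 2 female PBS, 2 male PBS, 3 female LPS and 3 male LPS libraries. The column of 1 male PBS library carries a replicate number that no sample label has, so it was assigned to the male PBS group only and is called the second male PBS library.

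The deposited files hold values of genes (24346 entries) and of long non-coding RNA (lncRNA) entries from the NONCODE annotation (123758 entries), both placed on the mm10 genome build. Per the file headers the values of each library are FPKM, fragments per kilobase and 1e6 mapped fragments. The authors also deposited a log2 column, which equalled log2(FPKM + 1) to within a standard deviation of 0.00457 over the 9 libraries compared. The deposited tables give the authors' ratio (fold change) between group means and a p-value for each pair of groups. The submitters' processing notes name TopHat, Cufflinks and edgeR without versions, and the mm10 build. The information sheet names a quantile normalization, but the deposited columns do not share 1 distribution. Read counts were not used here, as the values at hand are FPKM. The tests chosen for counts (edgeR, DESeq2 and limma-voom, with their scaling and filters) were therefore not run, and the total count of each library is unknown. A second sheet gives each library 1 of 3 dates without saying what was done on them. Date 1 holds replicate 1 of all 4 groups. Date 2 holds female PBS 2 and the other 4 LPS libraries, and date 3 holds the second male PBS library alone.

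All values were computed from the deposited FPKM, as log2(FPKM + 1), in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). Entries with a mean of at least 1 FPKM over the 10 libraries were tested, which left 12516 genes and 14357 lncRNA entries, genes and entries in separate fits. A model with 1 mean per group was fitted to all 10 libraries with limma (eBayes with a trend), with 6 residual degrees of freedom. The comparisons were LPS against PBS in each sex, their average over both sexes, the difference of the responses (male minus female), and male against female placenta within PBS and within LPS. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes or entries of a table, and an adjusted p under 0.05 was called. The text gives group values as mean FPKM ± SD over libraries and changes as log2 differences ± the standard error (SE) of the fit.

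The 37 gene lists, the comparisons, the tests, the naming rule and the first set of alternatives were chosen before the data were examined. The lists hold 1102 different genes, of which 1075 were in the gene table and 867 were tested. Some genes stand in more than 1 list. Some lists lost most of their members, which left 11 neutrophil markers, 11 chemokines and cytokines and 9 NK and T cell markers. As most libraries had LPS, a filter on the mean over all of them can favour members raised by LPS. Lists with fewer than 3 tested members (B cell markers and mitochondrially encoded genes) could not be tested, which left 35. Lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated per list, and with fry, each adjusted over the 35 lists. Camera compares a list with all other genes. At the preset correlation its p-value rests on the spread between genes, so a small value does not measure agreement between pools. With the libraries regrouped within sex it still called up to 15 lists. Fry asks whether the genes of a list move, on balance, in 1 direction. A separate list of 42 named lncRNAs had 28 members above the filter. The naming rule took the 8 higher and 8 lower genes with the largest change among those that passed, were in the upper part by mean value and had no overlap between the libraries of the groups compared (overlap was not asked about for the difference of the responses, and was asked within each sex for the average), all that passed where fewer than 8 passed in a direction, the 4 members with the smallest p of each called list or list with at least 3 members that passed, the 3 genes with the smallest p where none passed, and Xist with 4 Y-linked genes in every library. Of lncRNA entries it named the 4 higher and 4 lower with the largest change among those that passed and were in the upper part by mean value, and the members of the fixed list. For lncRNA entries the code also asked for no overlap, and named all that passed where fewer than 4 passed in a direction, which the fixed rule did not state. NONMMUG007510.2, called for the difference of the responses, falls outside this rule and was named after its values were seen.

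The method was tested on simulated data with the same groups and 200 changed genes. Noise was drawn for each gene on its own, without effects of date or library shared between genes. The shares recovered need not hold for the real data, where Madcam1 and Susd3 changed more than 2-fold in females and did not pass. Of the genes changed 2-fold, 85.1% were recovered for LPS in females, 68.7% in males, 95.5% in the average over sexes and 44.8% for the difference of the responses. Of those changed 1.5-fold, 44.8%, 47.8%, 74.6% and 17.9% were recovered. Of lncRNA entries changed 2-fold, 23.9% were recovered in females, 28.4% in males, 46.3% in the average and 1.49% for the difference of the responses, where 10.6% of those changed 3-fold were recovered. Depth could only be estimated, from the commonest product of FPKM and width among low values, taken as the worth of 1 fragment. It came to about 15 (in 1e6 fragments) in the 4 libraries of date 1, 23 in female PBS 2, 20 in the second male PBS library and 25 to 27 in the others, and to 3.4 to 7.2 for the lncRNA table. These estimates are approximate and allow no counting intervals. After the result was seen, each list was also set against the 200 genes outside it that were nearest in width to each member, whose mean log2 difference the text gives as that of genes of like width.

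The first set of alternatives was a pseudocount of 0.1, no filter, a minimum of 1.5-fold, and only the 2 groups compared. It also held each of the 10 libraries left out in turn and the other list tests. The replicate number was a further alternative, as a block over the numbered libraries and within treatment. Both replicate blocks leave out the second male PBS library, which was given no number, so male PBS 1 alone stood for male PBS. Summing entries that share a symbol had nothing to sum, as 0 symbols were duplicated. Alternatives chosen after seeing the data were date as a block, quantile normalization of the log2 values, and genes of at least 200 bases only. The second male PBS library is alone in its date. With date as a block, male PBS 1 is therefore the only male PBS library that informs a comparison. With 1 library left out, a group of 1 library was assumed to vary like the others. Other forms of the same libraries in the tables (un-logged, log10 and z-score columns, and the deposited log2 values of the second male PBS library), 32 columns in all, were not used. The plots were drawn with Python 3.11.15 and matplotlib 3.10.9.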

Results

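Gene expression was measured in pooled mouse placentas, female and male, 48 hours after the dams received PBS or LPS, a component of the bacterial cell wall that triggers inflammation. There were 2 female PBS, 2 male PBS, 3 female LPS and 3 male LPS libraries. The gene table listed 17865 to 18567 genes above 0 per library, with a depth estimated at 15 to 27 (in 1e6 fragments), and the lncRNA table listed 42914 to 53374 entries above 0. The title of the series asks whether LPS acts differently in female and male placenta.

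The first question was what LPS changed in placentas of both sexes. Madcam1, an adhesion molecule of vessel walls that binds lymphocytes (chromosome 10, 79664574 to 79668536 in mm10), went from 0.379 ± 0.0484 to 4.39 ± 1.03 FPKM in females (n = 2 and 3) and from 0.231 ± 0.0464 to 4.03 ± 1.39 in males (n = 2 and 3). Its average log2 change was 1.97 ± 0.17 (adjusted p = 0.00333). Ccl2, a chemokine that attracts monocytes (chromosome 11, 82035577 to 82037452), rose by 1.04 ± 0.12 (0.0272), from 1.88 ± 0.103 to 4.87 ± 0.703 FPKM in females and from 1.72 ± 0.270 to 4.74 ± 1.18 in males. Retnlg, a resistin-like protein made by neutrophils, rose by 1.18 ± 0.14 (0.0272) and Susd3, a membrane protein of the cell surface, by 0.89 ± 0.12 (0.0447). Trib3, a pseudokinase induced by stress of the endoplasmic reticulum (chromosome 2, 152337425 to 152344060), fell by 0.64 ± 0.08 (0.0359), from 4.37 ± 0.240 to 2.81 ± 0.356 FPKM in females and from 4.41 ± 0.268 to 2.13 ± 0.219 in males. Rasl11b, a small GTPase of the Ras family, fell by 0.54 ± 0.06 (0.0272) and the lncRNA 4833422C13Rik by 0.73 ± 0.09 (0.0319). For each of these 7 genes all 6 LPS libraries lay on 1 side of all 4 PBS libraries.

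These 7 genes and Scarna3b were the 8 genes called of 12516 (4 higher, 4 lower), where 1134 had an unadjusted p under 0.05 and 626 were due by chance. Scarna3b, a small RNA of Cajal bodies, was listed at 0 in 8 libraries and at 21.9 and 17.2 FPKM in the male PBS libraries. Madcam1 and Scarna3b kept their calls with any 1 library left out, but with a pseudocount of 0.1 Scarna3b was not called (adjusted p = 0.0550). The other 6 genes did not: the highest adjusted p was 0.1005 for Ccl2, 0.195 for Susd3 and 0.167 for Trib3 and 4833422C13Rik without female PBS 2, and 0.153 for Retnlg and Rasl11b without male LPS 2. The count was 2 without female LPS 1, male LPS 1 or male LPS 3, 3 without male LPS 2, 4 without female LPS 2, 5 without female LPS 3 and 13 without female PBS 1, of which 10 were RNAs under 200 bases. With date as a block 7 genes were called, Madcam1 (1.80) and Susd3 (1.07) higher and 5 short RNAs lower. Ccl2 (adjusted p = 0.131), Retnlg (0.0540), Trib3 (0.157), Rasl11b and 4833422C13Rik (0.131 each) then did not pass. Among genes of at least 200 bases alone 24 were called (11 higher, 13 lower), among them Csf3r, the receptor of the neutrophil growth factor G-CSF (adjusted p = 0.0331), S100a9, an abundant neutrophil protein (0.0360), and Timp1, an inhibitor of matrix proteases (0.0382). Over all 12516 genes Csf3r (0.0687), S100a9 (0.0770) and Timp1 (0.0687) did not pass.

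**Figure D1:**
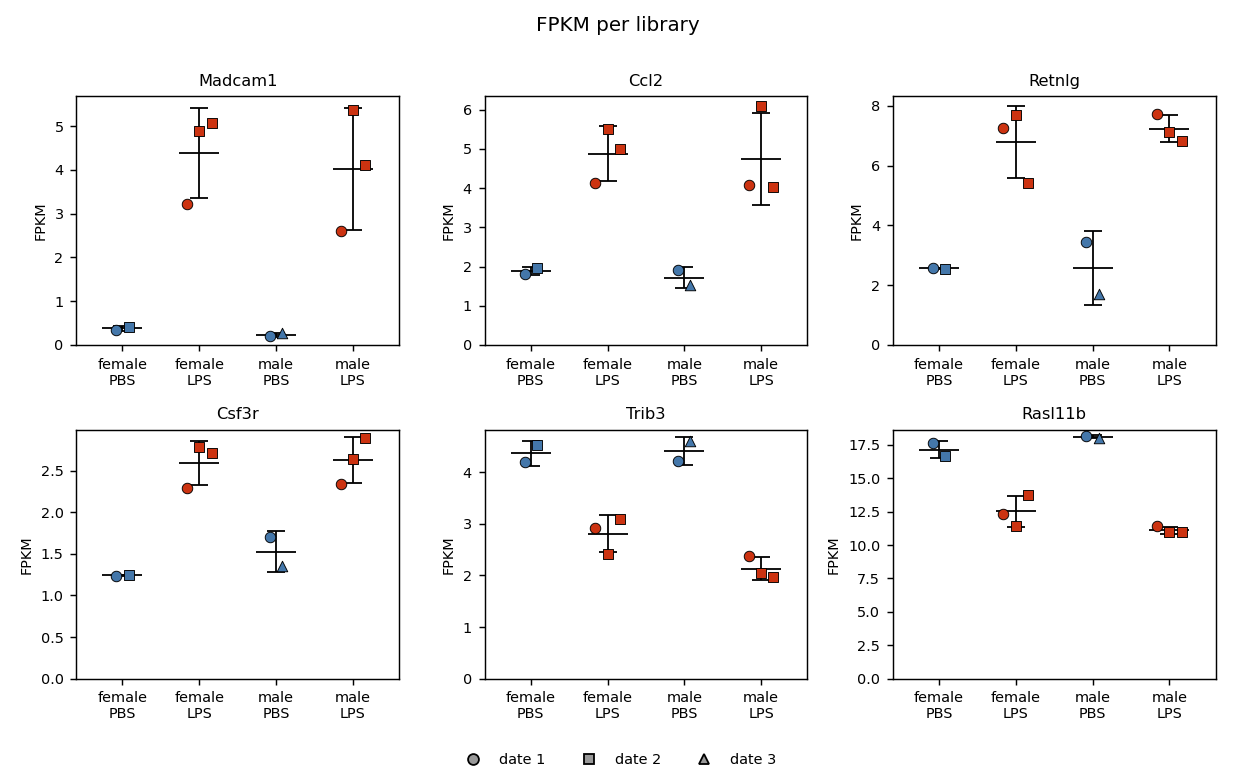
FPKM (y axis) of Madcam1, Ccl2, Retnlg, Csf3r, Trib3 and Rasl11b in each library, with bars for mean ± SD of the group and the symbol giving the date of the library. Madcam1 was at 0.198 to 0.413 FPKM in the 4 PBS libraries and at 2.60 to 5.37 in the 6 LPS libraries.

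Neutrophil markers rose as a group in the average over both sexes, by a mean log2 difference of 0.61 over 11 genes (camera adjusted p = 1.5e-11, adjusted p = 0.0428 with an estimated correlation, fry adjusted p = 0.00407). All 11 were higher. Adjusted over the list alone 8 passed and 3 did not, and Retnlg passed over all genes. S100a9 went from 13.2 ± 6.03 to 31.2 ± 7.37 FPKM in females and from 13.9 ± 1.37 to 27.9 ± 1.76 in males, and Csf3r from 1.24 ± 0.00590 to 2.59 ± 0.266 and from 1.53 ± 0.243 to 2.62 ± 0.278. The list was higher within date 1 by 0.47 in females and 0.44 in males (1 library against 1), and within date 2 by 0.59 in females (2 against 1). It was 0.50 with date as a block. Date 2 held no male PBS library and date 3 no LPS library.

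Genes of the endoplasmic reticulum stress response fell by a mean log2 difference of 0.22 over 28 genes, 27 of them lower (camera adjusted p = 6.7e-11, adjusted p = 0.400 with an estimated correlation). Trib3 and Herpud1, which serves the removal of misfolded proteins (-0.46 ± 0.11), passed adjusted over the list alone, and Trib3 over all genes. The list kept its call with any 1 library left out. Prolactin-like hormones and pregnancy-specific glycoproteins (Psg) of the junctional zone, the endocrine layer of the mouse placenta, were lower by 0.27 over 43 genes (34 lower, 5.0e-08, adjusted p = 0.504 with an estimated correlation). In limma 0 of the 43 passed adjusted over the list alone. Of 100 splits of the libraries within sex 25, the real one among them, had as large a mean difference (highest other 0.52), so chance was not excluded for this list by splits that take no account of date. It stood at -0.08 and was not called without male PBS 1 (adjusted p = 0.0699), and at -0.17 without female PBS 2, -0.47 without the second male PBS library and -0.57 with date as a block, called each time.

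Another 13 lists were called with camera, none with an estimated correlation (adjusted p = 0.445 to 0.785), so of all 16 only the neutrophil list kept its call in that test. Macrophage and monocyte markers were higher by 0.12 (Tyrobp, a signalling adaptor of myeloid cells, 0.37 ± 0.09), nutrient transporters by 0.08 (the glucose transporter Slc2a3, 0.56 ± 0.13), labyrinth syncytiotrophoblast markers by 0.07, histone genes by 0.15 and Y-linked genes by 0.20. The Y-linked value came from males alone (mean log2 level 2.89 in PBS, 3.29 in LPS). Females lay near the floor (0.0185 and 0.00846), so it is no change in both sexes. Lower were erythroid markers (-0.27), stroma, pericyte and smooth muscle markers (-0.14), spongiotrophoblast and glycogen cell markers (-0.11), endothelial markers (-0.10), oxidative stress and NRF2 genes (-0.09), matrix and remodelling genes (-0.09), hypoxia response genes (-0.07) and ribosomal proteins (-0.06). Adjusted over the list alone 2 matrix genes were higher and 5 lower, with Timp1 at 0.64 ± 0.10 and Timp2, a related inhibitor, at -0.40 ± 0.06, and in the other 12 lists 0 passed.

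Each of these 13 calls was lost without at least 1 library. Y-linked genes (0.19), endothelial markers (0.01) and ribosomal proteins (-0.02) lost the call without female PBS 1. Labyrinth markers (0.07), histone genes (0.11), Y-linked genes (0.21), erythroid markers (-0.24), spongiotrophoblast markers (-0.07), oxidative stress genes (-0.07) and matrix genes (-0.05) lost the call without female PBS 2, where endothelial markers (-0.20) and ribosomal proteins (-0.09) kept it. Macrophage markers (0.07), nutrient transporters (0.06), labyrinth markers (0.03), histone genes (-0.03), spongiotrophoblast markers (-0.07) and hypoxia genes (-0.05) lost the call without male PBS 1, where Y-linked genes (0.36), stroma markers (-0.25), endothelial markers (-0.16), matrix genes (-0.14) and ribosomal proteins (-0.09) kept it. Nutrient transporters (0.09), Y-linked genes (0.03), erythroid markers (-0.20), stroma markers (-0.04), endothelial markers (-0.04), oxidative stress genes (-0.05), matrix genes (-0.03) and ribosomal proteins (-0.02) lost the call without the second male PBS library, where labyrinth markers (0.12) and histone genes (0.32) kept it. Labyrinth markers (0.08), histone genes (0.10), Y-linked genes (0.20), spongiotrophoblast markers (-0.08) and ribosomal proteins (-0.06) lost the call without female LPS 1. Macrophage markers (0.10), labyrinth markers (0.09), Y-linked genes (0.19), oxidative stress genes (-0.08) and ribosomal proteins (-0.04) lost the call without female LPS 2, where histone genes (0.23) kept it. Nutrient transporters (0.06), labyrinth markers (0.05), histone genes (0.12), Y-linked genes (0.20) and endothelial markers (-0.07) lost the call without female LPS 3. Y-linked genes (0.20) lost the call without male LPS 1. Y-linked genes (0.17) lost the call without male LPS 2. Nutrient transporters (0.06), labyrinth markers (0.05), histone genes (0.09), spongiotrophoblast markers (-0.10), endothelial markers (-0.08) and ribosomal proteins (-0.04) lost the call without male LPS 3. Erythroid markers (-0.28), nutrient transporters (0.07), oxidative stress genes (-0.05), matrix genes (-0.02), Y-linked genes (0.02), endothelial markers (0.04), stroma markers (0.00351) and ribosomal proteins (0.01) lost the call with date as a block.

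Several groups often tied to LPS were not called in this average. Toll-like receptor and NF-kB genes had a mean change of -0.02 (adjusted p = 0.481), chemokines and cytokines 0.06 (0.920), interferon response genes 0.07 (0.130), acute phase and antimicrobial genes 0.01 (0.568), antigen presentation -0.01 (0.789), and complement and coagulation -5.8e-05 (0.920). Among acute phase genes 4 were higher adjusted over the list alone. As fixed, this list shares S100a8, S100a9, Lcn2 and Chil3 with the neutrophil list, so the lists are not independent. Only 11 chemokines and cytokines of the fixed list were tested, and its other members, not having a mean of at least 1 FPKM, were not. Of the 11 Ccl2 passed over all genes, and 1 was higher and 1 lower adjusted over the list alone.

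In female placenta alone no single gene was called. Camera at its preset correlation called lower hormone genes of the junctional zone and higher neutrophil markers, and with an estimated correlation neither list was called (adjusted p = 0.697 and 0.276). Pregnancy-specific glycoproteins are secreted into the maternal blood in large amounts. Psg23 (chromosome 7, 18606343 to 18616501) went from 4047 ± 905 to 2216 ± 76.2 FPKM (n = 2 and 3), Psg21 from 4001 ± 601 to 2109 ± 280 and Psg26 from 944 ± 231 to 483 ± 82.7. As a group the 43 hormone genes fell by a mean log2 difference of 0.65, with 41 of them lower (camera adjusted p = 5.1e-17, adjusted p = 0.697 with an estimated correlation, fry adjusted p = 0.446). Adjusted over the list alone 23 were lower, 0 higher and 20 did not pass, and over all genes 0 passed. The difference was -0.65 within date 1 and -0.75 within date 2.

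Neutrophil markers rose in females by 0.55 over 11 genes (8.9e-06, adjusted p = 0.276 with an estimated correlation, fry adjusted p = 0.0413), with 10 higher and 4 of these adjusted over the list alone. Endoplasmic reticulum stress genes fell by 0.29 over 28 genes (6.6e-09, adjusted p = 0.590 with an estimated correlation), with 24 lower and 4 of these adjusted over the list alone, and stood at -0.17 without female PBS 2. The chaperones Hspa5 (from 786 ± 176 to 526 ± 48.5 FPKM) and Hsp90b1 (from 543 ± 146 to 341 ± 31.1) were 2 of these 4. The other 6 lists called in females lost their calls with an estimated correlation (adjusted p = 0.697 to 0.804), and 0 of their genes passed adjusted over the list alone. Spongiotrophoblast and glycogen cell markers were at -0.22, with Tpbpa, a marker of the spongiotrophoblast, from 8084 ± 1176 to 4737 ± 547 FPKM. Erythroid markers were at -0.49, NK and T cell markers at -0.20, macrophage and monocyte markers at 0.17, histone genes at 0.38 (other genes of like width 0.12), and yolk sac and visceral endoderm markers at 0.40. NK and T cell markers (-0.22) and macrophage markers (0.14) lost the call without female PBS 1, where yolk sac markers (0.87) kept it. Spongiotrophoblast markers (-0.15), erythroid markers (-0.44), NK and T cell markers (-0.18) and yolk sac markers (-0.07) lost the call without female PBS 2. Spongiotrophoblast markers (-0.16), NK and T cell markers (-0.13) and macrophage markers (0.17) lost the call without female LPS 1. NK and T cell markers (-0.21), macrophage markers (0.13) and yolk sac markers (0.37) lost the call without female LPS 2. Macrophage markers (0.16) lost the call with date as a block.

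In females limma called 0 of 12516 genes (smallest adjusted p = 0.106), where 1264 had an unadjusted p under 0.05. The 3 genes with the smallest p, none of which passed, were Madcam1 (1.95 ± 0.24), Susd3 (1.34 ± 0.17, from 9.37 ± 1.64 to 25.3 ± 3.06 FPKM) and Kcnq4, a potassium channel subunit (0.78 ± 0.13). With date as a block Madcam1 (adjusted p = 0.0415), Susd3 (0.0459) and the small nucleolar RNA Snora16a were called. Among genes of at least 200 bases Madcam1 (0.0307) and Susd3 (0.0307) were called. The count was 9 without female PBS 1, 5 without female PBS 2, 2 without male PBS 1, the second male PBS library or female LPS 2, and 1 without female LPS 3 or male LPS 1. RNAs under 200 bases made up all 9 of the first and 4 of the 5 in the second.

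In male placenta neutrophil markers rose as well, by 0.67 over 11 genes (camera adjusted p = 1.3e-07, adjusted p = 0.121 with an estimated correlation, fry adjusted p = 0.0227), all 11 higher and 3 of them adjusted over the list alone. Limma called 3 of 12516 genes, with 1044 at an unadjusted p under 0.05. Madcam1 rose by 1.99 ± 0.24 (adjusted p = 0.0418) and did not differ from its change in females (interaction 0.04 ± 0.33). Lars2, the leucyl-tRNA synthetase of mitochondria (chromosome 9, 123366940 to 123462664), fell by 2.27 ± 0.24 (0.0234), from 59.4 ± 9.57 to 11.9 ± 3.78 FPKM (n = 2 and 3), where female PBS and LPS stood at 13.7 ± 1.43 and 13.6 ± 2.43 (interaction -2.25 ± 0.34, adjusted p = 0.436). Scarna3b was listed at 0 in all 3 male LPS libraries. Madcam1 lost its call without 8 of the 10 libraries in turn (adjusted p of up to 0.337, without male LPS 3) and Lars2 without 6 (up to 0.133, without male LPS 2). The count was 1 without female PBS 1, female PBS 2, female LPS 3 or male LPS 2, and 5 without male PBS 1 or the second male PBS library. With date as a block 5 genes were called, all RNAs under 200 bases, and neither Madcam1 (0.169) nor Lars2 (0.0915) passed.

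Another 8 lists were called in males, none with an estimated correlation (adjusted p = 0.537 to 0.623). Endothelial markers were lower by a mean log2 difference of 0.23 (26 of 30 lower), with Sox18, a transcription factor of endothelial cells, at -0.57 ± 0.19. Angiogenesis and growth factors were at -0.15, with Angpt2, a ligand of the receptor Tie2, from 14.5 ± 0.193 to 8.22 ± 1.32 FPKM. Stroma markers were at -0.24, matrix and remodelling genes at -0.14, ribosomal proteins at -0.20 (other genes of like width -0.10), yolk sac and visceral endoderm markers at -0.52, endoplasmic reticulum stress genes at -0.15 and Y-linked genes at 0.41. Adjusted over the list alone 1 stress gene was lower and 0 genes of the other 7 lists passed. Stress genes (-0.11) lost the call without male PBS 1, where endothelial markers (-0.36), stroma markers (-0.46), matrix genes (-0.26), yolk sac markers (-0.91) and Y-linked genes (0.74) kept it. Endothelial markers (-0.11), angiogenesis factors (-0.08), stroma markers (-0.02), matrix genes (-0.03), yolk sac markers (-0.14) and Y-linked genes (0.07) lost the call without the second male PBS library, where ribosomal proteins (-0.13) kept it. Angiogenesis factors (-0.14) lost the call without male LPS 3. Yolk sac markers (-0.04), angiogenesis factors (-0.04), matrix genes (-0.02), ribosomal proteins (-0.08), Y-linked genes (0.06), endothelial markers (0.02) and stroma markers (0.04) lost the call with date as a block. Junctional-zone hormone genes had a mean of 0.10 in males (adjusted p = 0.257). It was -0.29 without the second male PBS library, 0.49 without male PBS 1, -0.45 with date as a block and -0.32 within date 1. The values of -0.29, -0.45 and -0.32 all rest on male PBS 1 as the only male control, so they are not separate results.

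The direct question of the series, whether the responses of the sexes differ, was tested as the male minus the female change. Junctional-zone hormone genes differed by a mean log2 difference of 0.75 over 43 genes (41 positive, camera adjusted p = 1.4e-12, adjusted p = 0.802 with an estimated correlation, fry adjusted p = 0.471). In limma 0 of them passed adjusted over the list alone or over all genes. Prl7b1, a prolactin-like hormone (0.82 ± 0.25), and Ceacam3, a relative of the Psg genes (0.90 ± 0.27), had the smallest p of the list. The difference was 0.36 without the second male PBS library, 1.13 without male PBS 1 and 0.24 with date as a block. The values of 0.36 and 0.24 both rest on male PBS 1 as the only male control. Neutrophil markers were at 0.12 and not called (adjusted p = 0.798).

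**Figure D2:**
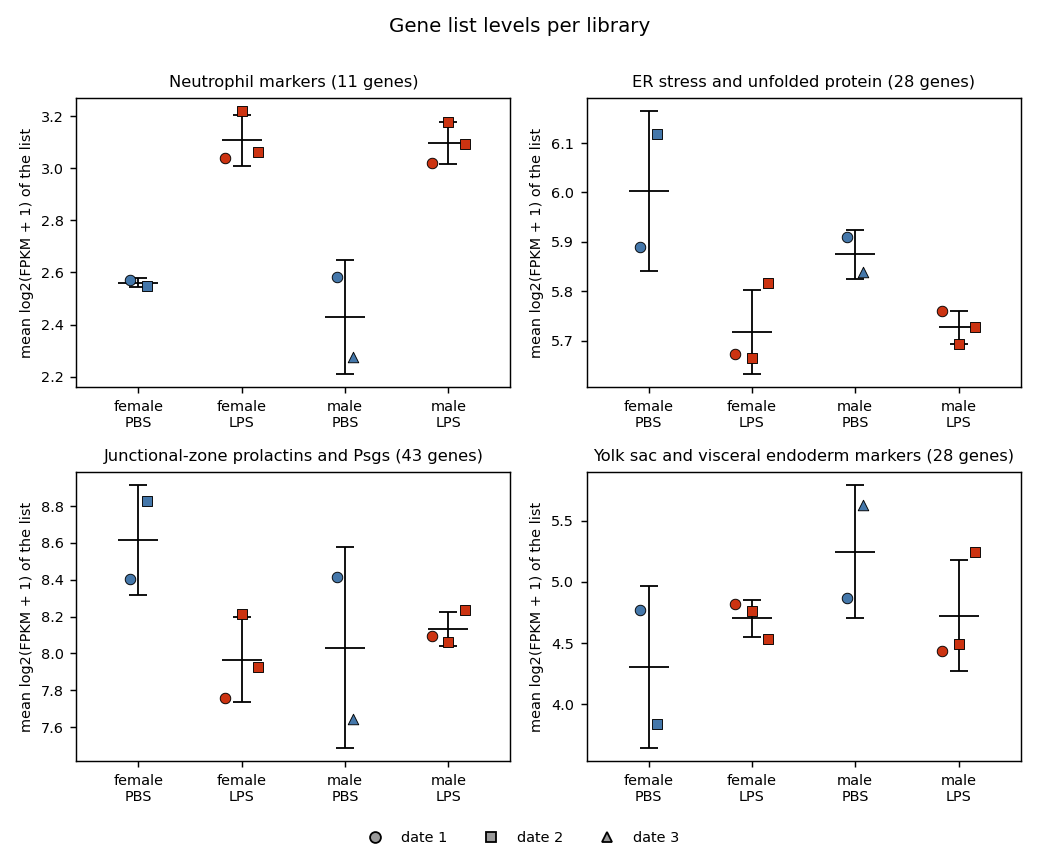
Mean log2(FPKM + 1) per library (y axis) of the neutrophil, endoplasmic reticulum stress, junctional-zone and yolk sac lists, with bars for mean ± SD of the group and the symbol giving the date. Neutrophil markers were at 2.27 to 2.58 in the 4 PBS libraries and 3.02 to 3.22 in the 6 LPS libraries, and the second male PBS library had the lowest junctional-zone level (7.65) and the highest yolk sac level (5.63).

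Yolk sac and visceral endoderm markers differed by -0.93, ribosomal proteins by -0.28, endothelial markers by -0.27, histone genes by -0.46, and X-inactivation and escape genes by 0.37. All 5 were called with camera, none with an estimated correlation (adjusted p = 0.802 to 0.805), and 0 of their genes passed adjusted over the list alone. Other genes of like width stood at -0.16 for ribosomal proteins and at -0.25 for histone genes. Yolk sac markers (-1.39) and endothelial markers (-0.48) moved but kept the call without female PBS 1. Endothelial markers (-0.07), histone genes (-0.37) and X-inactivation genes (0.26) lost the call without female PBS 2, where yolk sac markers (-0.46) kept it. Histone genes (-0.80) moved but kept the call without male PBS 1. Endothelial markers (-0.15), histone genes (-0.11) and X-inactivation genes (0.20) lost the call without the second male PBS library, where yolk sac markers (-0.54) kept it. Endothelial markers (-0.26) lost the call without female LPS 2. Endothelial markers (-0.05), histone genes (-0.03) and X-inactivation genes (0.16) lost the call with date as a block. For single genes limma called 1 of 12516, Scarna3b (not called with a pseudocount of 0.1, adjusted p = 0.377), with 1173 at an unadjusted p under 0.05. The count was 10 without female PBS 1, 6 without female PBS 2, 5 without male PBS 1, 4 without the second male PBS library, and 2 without female LPS 2 or female LPS 3. Among genes of at least 200 bases 0 were called.

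Male and female PBS placentas were compared to see how the sexes differ without LPS. The clearest differences lay on the sex chromosomes. The Y-linked genes Ddx3y (12.9 ± 4.77 FPKM), Eif2s3y (18.8 and 9.28 in the 2 libraries), Uty (3.49 ± 1.72) and Kdm5d (2.63 ± 0.369) were present in male PBS, while Uty and Kdm5d were listed at 0 in both female PBS libraries, and Ddx3y and Eif2s3y at 0 in 1 of them and at 0.00862 and 0.0983 FPKM in the other. Xist, the RNA that silences 1 X chromosome in females (chromosome X, 103460373 to 103483233), was at 55.6 ± 12.4 FPKM in females and 3.42 ± 1.15 in males (n = 2 each, -3.69 ± 0.27, adjusted p = 0.000351). Limma called 8 of 12516 genes, with 652 at an unadjusted p under 0.05: the 4 Y-linked genes, Scarna3b and Lars2 (2.04 ± 0.26, 0.0361) higher in males, and Xist and BC048679 (-1.12 ± 0.15, 0.0417) lower. Without female PBS 1 14 genes were called, of which 10 were RNAs under 200 bases. Lars2 and BC048679 lost their calls without 7 and 8 of the 10 libraries in turn (adjusted p of up to 0.399 without female PBS 2 and 0.273 without the second male PBS library), and Uty without female PBS 1 (0.0520) or female PBS 2 (0.0743).

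Of 35 lists 9 were called between the sexes in PBS. Y-linked genes (2.87, adjusted p = 0.0897 with an estimated correlation) and X-inactivation and escape genes (-0.81, 0.193) were called in fry as well (0.000130 and 0.0249), and 4 Y-linked genes were higher and 7 of 10 X-linked genes lower adjusted over the list alone. The other 7 lists had an adjusted p of 0.605 to 0.670 with an estimated correlation. Junctional-zone hormone genes were at -0.58 in males, NK and T cell markers at -0.40 and endoplasmic reticulum stress genes at -0.13. Granzyme G, a protease of uterine NK cells (Gzmg, 33.3 ± 1.02 FPKM in females and 23.7 ± 2.33 in males), was lower adjusted over the list alone. Yolk sac markers were at 0.94, ribosomal proteins at 0.18, endothelial markers at 0.18 and nuclear genes of oxidative phosphorylation at 0.11. Within date 1 (1 library of each sex) the mean log2 value of yolk sac markers was 4.86 in male and 4.77 in female PBS. That of junctional-zone hormone genes was 8.42 and 8.40 there. Other genes of like width stood at 0.09 for ribosomal proteins and at 0.08 for oxidative phosphorylation. Genes under 1000 bases had a median log2 difference of -0.130 from the other libraries in female PBS 2 and of 0.134 in the second male PBS library, and these were the lowest and highest PBS libraries for both lists (8.46 and 8.76 for ribosomal proteins, 5.90 and 6.12 for oxidative phosphorylation). Stress genes (-0.24), endothelial markers (0.38) and oxidative phosphorylation (0.18) moved but kept the call without female PBS 1. Stress genes (-0.01), endothelial markers (-0.03) and oxidative phosphorylation (0.03) lost the call without female PBS 2, where junctional-zone genes (-0.37), yolk sac markers (0.48) and ribosomal proteins (0.11) kept it. Junctional-zone genes (-0.97), NK and T cell markers (-0.63) and endothelial markers (0.30) moved but kept the call without male PBS 1. Endothelial markers (0.05) and oxidative phosphorylation (0.06) lost the call without the second male PBS library, where junctional-zone genes (-0.20), NK and T cell markers (-0.16), yolk sac markers (0.56) and ribosomal proteins (0.11) kept it. NK and T cell markers (-0.09), junctional-zone genes (-0.07), stress genes (-0.06), oxidative phosphorylation (0.04), ribosomal proteins (0.07) and endothelial markers (-0.05) lost the call with date as a block.

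Male and female LPS placentas, the only comparison with 3 libraries on each side, differed in genes of the sex chromosomes. Ddx3y (4.13 ± 0.16), Eif2s3y (4.35 ± 0.22), Kdm5d (2.10 ± 0.11) and Uty (2.55 ± 0.18) were higher in males and Xist lower (-3.28 ± 0.22, 50.1 ± 12.7 against 4.24 ± 1.02 FPKM). These 5 were all that limma called, with 505 at an unadjusted p under 0.05, and all 5 were called with date as a block and with any 1 library left out. Y-linked genes kept their call with an estimated correlation (3.28, adjusted p = 0.0424). The other 6 lists called did not (adjusted p = 0.969): histone genes (-0.31), X-inactivation and escape genes (-0.44), NK and T cell markers (-0.22) and ribosomal proteins (-0.10) were lower in males, and junctional-zone hormone genes (0.16) and erythroid markers (0.23) higher. Adjusted over the list alone 4 Y-linked genes were higher, and 2 X-linked genes and 1 NK and T cell marker lower. Other genes of like width stood at -0.08 for ribosomal proteins and at -0.11 for histone genes. Erythroid markers (0.23) lost the call without male PBS 1. Erythroid markers (0.23) lost the call without the second male PBS library. Junctional-zone genes (0.06) lost the call without female LPS 1. X-inactivation genes (-0.36), NK and T cell markers (-0.21) and erythroid markers (0.37) lost the call without female LPS 2, where histone genes (-0.46) and junctional-zone genes (0.29) kept it. Ribosomal proteins (-0.06) and erythroid markers (0.12) lost the call without female LPS 3. NK and T cell markers (-0.16) lost the call without male LPS 1, where erythroid markers (0.35) kept it. Erythroid markers (0.07) lost the call without male LPS 2, where histone genes (-0.18) kept it. Ribosomal proteins (-0.08) lost the call without male LPS 3. Erythroid markers (0.23) lost the call with date as a block.

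Among lncRNAs, 2 of 14357 entries were called for LPS in females, 5 in males, 1 in the average and 5 for the difference of the responses, where 624, 1531, 1018 and 1125 had an unadjusted p under 0.05 and 718 were due by chance. What these RNAs do is not known. Most called entries were near 0 in a whole PBS group. NONMMUG020742.2 (chromosome 19, 7472708 to 7476413) was at 5.93 and 7.56 FPKM in female PBS and at 0.0533 to 0.0543 in the other 8 libraries, while NONMMUT033752.2 on the same strand and start was at 0.00775 and 0.155 and at 6.22 to 9.64. In male PBS NONMMUT057728.2 was at 0.0238 and 0.00780, NONMMUT062675.2 at 0.00208 and 0.00285 and NONMMUT069619.2 at 0.872 and 0.00145, against 3.86 to 13.9, 3.82 to 25.5 and 2.96 to 11.5 elsewhere. NONMMUG044321.2 (chromosome 9, 123461799 to 123462187), an entry within the bounds of Lars2, was at 4294 and 4777 FPKM in male PBS and at 413 to 974 in the other 8.

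The number of lncRNA entries called depended on single libraries. In females it was 5 without female PBS 1 or female PBS 2 or male LPS 3, 4 without male LPS 1, 8 without male LPS 2. In males it was 1 without female PBS 1 or female PBS 2, 20 without male PBS 1, 3 without female LPS 1 or female LPS 2, 11 without male LPS 1. In the average it was 0 without female PBS 1 or female PBS 2 or male PBS 1 or male LPS 2, 8 without the second male PBS library, 2 without female LPS 3, 4 without male LPS 1 or male LPS 3. For the difference of the responses it was 0 without female PBS 1 or female LPS 2, 1 without female PBS 2 or male LPS 1, 12 without male PBS 1, 2 without female LPS 1 or male LPS 3, 3 without female LPS 3. With date as a block the 4 counts were 2, 2, 2 and 3. Of the 28 named lncRNAs tested, limma called 0 for LPS in either sex, in the average or for the difference, over all genes and adjusted over the list alone. H19, an imprinted RNA abundant in placenta, had a log2 change of 0.01 ± 0.13 in the average and Malat1, a nuclear RNA, of 0.00386 ± 0.13. Xist passed in both comparisons of the sexes.

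The authors' own table, by their p under 0.05 and at least 2-fold, holds 6 higher and 9 lower genes for LPS in females, 5 and 10 in males, 5 and 5 for male against female PBS, and 4 and 1 for male against female LPS. For lncRNA entries it holds 70 and 101 for LPS in females, 71 and 143 in males, 123 and 85 for male against female PBS, and 45 and 58 for male against female LPS. The authors' p was used as given, so these counts cannot be set beside the adjusted calls above. For LPS in females it was under 0.05 for 1154 of 24346 genes and 3061 of 123758 lncRNA entries, whatever the fold.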

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

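Apart from the splits of the libraries, the tests here and in the observations were chosen after the data were examined. For the switched entries and the median of long transcripts the prediction was written before the value of the test was computed, and for the others after the result was seen.

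The junctional-zone hormone genes differed between the sexes in their response to LPS, by a mean log2 difference of 0.75 that was called with camera at its preset correlation but not with an estimated correlation (adjusted p = 0.802) or in fry (0.471), and 0 of the 43 genes passed. Without the second male PBS library the value was 0.36, called at the preset correlation, so that library alone could account for a large part of the difference. A wrong treatment label on it is excluded by its neutrophil level of 2.27, as the lowest LPS library had 3.02. More yolk sac tissue in some pools cannot be told apart from a change in the hormone genes: the 2 lists had r = -0.61 over the 10 libraries (permutation p = 0.0578), but a rank correlation of -0.26 (0.473), and r = 0.34 without female PBS 2 and the second male PBS library. The value therefore may rest on the make-up of single pools, and a difference between the sexes was not shown.

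Neutrophil markers were higher after LPS in both sexes, by 0.61. If the pools are independent, chance was unlikely for this list taken alone. Of 100 splits of the libraries within sex only 1, the real one, had as large a value (highest other 0.47). That is the smallest share 100 splits can give, the list was 1 of 35 tested, and the splits take no account of date. Female and male pools may share mothers, and the splits take no account of that either. The list was higher within date 1 by 0.47 in females and 0.44 in males, within date 2 by 0.59 in females, and by 0.50 with date as a term. These values argue against date as the whole cause. In males they rest on 1 library against 1, so date is not excluded there. More blood in the LPS pools cannot be told apart: erythroid markers were at -0.27 in the average, a call lost with date as a term. They were at -0.49 in females and -0.05 in males, where they were not called. As a hypothesis, neutrophils may enter the placenta or its blood spaces after LPS, as the value of 0.50 with date as a term leaves it. Cell numbers were not measured.

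Most lncRNA entries called between groups were near 0 in a whole PBS group. Reads of 1 locus divided between overlapping entries could produce this: at 4 of 4 called loci whose overlapping partners were not called themselves, the partners moved the other way with no overlap between the libraries of the groups (log2 change of -0.55 to -10.1). At all called loci with partners, FPKM times span was summed over the overlapping entries. The log2 change with LPS in 1 sex was then -0.42 to 0.40, against 4.09 to 13.1 in size for the called entries alone. These loci as a whole thus changed far less than the entries. NONMMUG044321.2 had no such partner. Values estimated group by group by the authors cannot be told apart from this, as 3 of 43 other pairs of libraries had as many switched entries as the lower of the PBS groups (11 and 13, highest other 14). The LPS groups showed no excess of such entries: female LPS held 1 and male LPS 0, where other sets of 3 libraries had a median of 1 (highest 7). For the number of entries called in the average, chance cannot be excluded, as 72 of 100 splits had as many (real 1, highest other 20). The split with 20 set 4 libraries of date 2 against the rest.

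If the pools are independent, chance was unlikely for the number of genes called in the average (1 of 100 splits, real 8, highest other 3). However, 100 splits can give no smaller share. For the number of lists that camera called at its preset correlation the real split was barely ahead (1 of 100, real 16, highest other 15), so chance is not excluded. Of these 16 only the neutrophil list was called with an estimated correlation. For the lower junctional-zone genes in the average chance cannot be excluded, as 25 of 100 splits had as large a value (real 0.27, highest other 0.52); this prediction was written after the result was seen. These splits take no account of date, or of mothers that female and male pools may share. The second male PBS library, alone in date 3, had the lowest level (7.65), and the list was lower by 0.65 in females and 0.32 in males within date 1, by 0.75 in females within date 2 and by 0.57 with date as a term. For genes between male and female LPS placenta the splits were too few (1 of 10, real 5, highest other 1), and for lists as well (6 of 10, real 7, highest other 12).

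Scarna3b had a difference of the responses of -4.35. NONMMUG007510.2 had 2.01. NONMMUG020742.2 had 2.87. NONMMUT033752.2 had -2.82. NONMMUT057728.2 had 4.39. NONMMUT069619.2 had 3.72. NONMMUG020742.2 and NONMMUT033752.2 overlap on the same strand and are not separate results. Summed over overlapping entries, their locus changed with LPS by a log2 difference of 0.24 in females. In males the summed change was 0.40 for NONMMUG007510.2, -0.10 for NONMMUT057728.2 and -0.42 for NONMMUT069619.2. A difference between the sexes was therefore not shown for these loci as a whole. Endothelial markers had -0.27, yolk sac and visceral endoderm markers -0.93, ribosomal proteins -0.28, histone genes -0.46, and X-inactivation and escape genes 0.37.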

How the results depend on the processing

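The date block, quantile normalization and the minimum of 200 bases were chosen after the result was seen. The tests on counts (edgeR, DESeq2, limma-voom) could not be run on FPKM. Where a value moved, the cause was not tested. A count was taken as the same where the larger was at most 1.5 times the smaller, whether or not the same genes were called. Over all settings 88 counts were the same by this rule and 88 moved. For lists 802 values stayed on the same side of the threshold, 256 lost a call, 1 gained one and 24 changed direction.

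With an estimated correlation the mean differences are the same and the calls are lost: neutrophil markers 0.55 in females (0.276) and 0.67 in males (0.121), junctional-zone genes -0.65 in females (0.697), -0.27 in the average (0.504) and 0.75 for the difference of the responses (0.802), stress genes -0.29 (0.590), -0.15 (0.623) and -0.22 (0.400), and between the sexes in PBS yolk sac markers 0.94 (0.605) and Y-linked genes 2.87 (0.0897). In fry the call was lost for junctional-zone genes in females (0.446), the average (0.447) and the difference (0.471), for stress genes in females (0.190), males (0.422) and the average (0.136), and for yolk sac markers in PBS (0.451).

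The deviations of libraries with the same replicate number had a correlation over 0.1 in 3 of 10 pairs. Pairs of a PBS and an LPS library cannot share mothers, and values over 0.1 came from such pairs too (0.138 and 0.121). Female and male LPS libraries had 0.135, 0.0924 and 0.0531 for numbers 1, 2 and 3, and female and male PBS 1 had -0.116. Pairing within treatment was therefore not settled. Number 1 goes with date 1, so a shared batch cannot be told apart from pairing there. Both replicate blocks leave out the second male PBS library, so shifts in them include the loss of that library. With the block within treatment, male and female PBS are compared through replicate 1 of each sex alone. With the replicate number as a block, 1 gene was called in females, 5 in males and 4 for the difference, and 1 lncRNA entry in males and 1 for the difference. In that block junctional-zone genes in males were at -0.44 (1.3e-10), endothelial markers at 0.0225 in males, 0.0539 in the average and -0.0345 between the sexes in PBS, stroma markers in males at 0.0355 and histone genes at 0.0465 for the difference. With the block within treatment 10 genes were called for the difference and 16 between the sexes in PBS, and 0 lncRNA entries for the difference. Endothelial markers were then at 0.0603 for the difference and -0.16 in PBS, and junctional-zone genes (0.0139), yolk sac markers (0.0940), stress genes (0.0209) and oxidative phosphorylation (-0.0123) in PBS lay near 0.

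With date as a block the gene counts were 3 in females, 5 in males and 4 for the difference, and the lncRNA counts 2 in males, 2 in the average and 3 for the difference. Junctional-zone genes in males were at -0.45, endothelial markers at 0.0172 in males, 0.0433 in the average and -0.0451 in PBS, stroma markers at 0.0414 in males and 0.00351 in the average, and ribosomal proteins in the average at 0.00616. With a pseudocount of 0.1, 1 gene was called in females and 0 for the difference, and 9, 11, 12 and 8 lncRNA entries in females, males, the average and the difference. With no filter 1 gene was called in males and 2 in the average, and 69, 78, 110 and 110 lncRNA entries. After quantile normalization stress genes in males were at -0.12 (0.0516) and ribosomal proteins in the average at 0.0386, and 2 lncRNA entries were called in males. With genes of at least 200 bases 2 were called in females, 24 in the average and 0 for the difference. With only the groups compared 2 genes were called in females and 5 between the sexes in PBS, and 12 and 2 lncRNA entries in females and males.

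With 1 library left out the gene counts ranged from 0 to 9 in females, 1 to 5 in males, 2 to 13 in the average, 1 to 10 for the difference, 6 to 14 between the sexes in PBS and 5 to 6 in LPS, and the lncRNA counts from 2 to 8, 1 to 20, 0 to 8 and 0 to 12. Junctional-zone genes ranged from -0.86 to -0.44 in females, -0.29 to 0.49 in males, -0.47 to -0.0811 in the average and 0.36 to 1.13 for the difference, neutrophil markers in the average from 0.53 to 0.68, endothelial markers from -0.20 to 0.00505 in the average and -0.0314 to 0.38 in PBS, histone genes in the average from -0.0251 to 0.32, yolk sac markers in females from -0.0675 to 0.87 and stress genes in males from -0.18 to -0.11.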

Other observations

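Several groups of genes were not called in the average over both sexes and have not been described so far. NK and T cell markers were at -0.11 (adjusted p = 0.0746), angiogenesis and growth factors at -0.07 (0.0576), yolk sac and visceral endoderm markers at -0.06 (0.589), nuclear genes of oxidative phosphorylation at 0.02 (0.568) and X-inactivation and escape genes at 0.02 (0.946).

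The tests of Lars2, of Xist and of width classes were chosen after the result was seen. Lars2 was higher in the male PBS libraries than in the other 8. In those 8 Lars2 and the short entry NONMMUG044321.2 inside it had r = 0.94 (exact permutation p = 0.00107), and 0.86 without the 2 farthest libraries. The signal of 1 short stretch may therefore make up the Lars2 value, which the r of 0.94 fits.

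Y-linked genes and Xist were lower in the second male PBS library than in the first. Female placentas in the pool are excluded, as Xist was at 2.60 FPKM, below the lowest other male library (3.39). Long transcripts were somewhat lower in that library: against the first male PBS library the median log2 difference was 0.103 for genes under 1000 bases and -0.0733 at 6000 bases and above (-0.0219 over all genes at least as wide as the narrowest of these 5). Xist, Ddx3y, Eif2s3y and Uty lay below the 5th percentile of genes in the same width class, which argues against this trend as the whole cause. It is not excluded, as 1 library was set against 1 and some genes of each class were as low. Their share was 4.48% for Xist, 1.25% for Ddx3y, 0.901% for Eif2s3y and 0.580% for Uty. For Kdm5d the cause cannot be told (-0.208, where 32.1% of such genes were as low).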
